A study of Mus musculus with 18 samples.

How the data were processed

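The series holds 18 samples of mouse embryonic stem (ES) cells and embryoid bodies (EBs), of which 6 are RNA-seq libraries and 12 are ChIP-seq samples of histone modifications. The RNA-seq libraries are analysed here, and the ChIP-seq samples are not analysed here. Per the labels' protocols, RNA was extracted with Trizol and made into libraries with the TruSeq RNA version 2 kit, a poly(A) selection kit that does not mark strand. Reads of a gene and of an antisense partner therefore cannot be told apart.

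The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of a library) for 26439 coding and 3412 non-coding RefSeq transcripts. The authors aligned reads with TopHat and quantified them with Cuffdiff on the mm9 genome build, per the submitters' processing notes. Versions, options, the annotation release and the scaling between libraries are not given in the sources used here. Transcripts of the same gene have separate values, so the authors' software divided reads between isoforms, and an isoform near 0 can be a product of that division. An exact 0 is reported only as listed at 0, and no fold is given against it.

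Accessions were matched to gene symbols through a RefSeq table of the GRCm38.p6 assembly, used for names only. A symbol was found for 29296 transcripts and not for 555, which kept their accession. Of the resulting 23421 symbols, 3939 had several transcripts, and the transcript with the highest mean over the 6 libraries was used. Coordinates are those of the deposited table on mm9, written from 1.

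Each comparison sets 1 library against 1 library, and there are no replicates. No test was run and no p-value or standard error is given. A gene counted as expressed at an FPKM of at least 1 in at least 1 of the 4 E36 libraries, or of the 2 libraries compared where E14 cells were involved. The difference of log2(FPKM + 1) between libraries was computed with a pseudocount of 1, which understates the change of weakly expressed genes. A gene was called higher or lower by the size rule where that difference was at least 1 in size. All differences below are on this log2(FPKM + 1) scale. There were 7 comparisons, including the difference between the Eed effects in EBs and ES cells and a yardstick between control ES cells of different lines.

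A total of 34 gene lists holding 990 genes were fixed before the data were examined, as were the comparisons, the size rule and most of the settings varied below. For each list the median difference over its expressed members was set against 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart at or under percentile 2.5, or equally far into the upper tail. The percentile describes these libraries and is not a test, and it is relative to other genes of the same libraries, so a shift common to all genes does not enter it. Named genes follow a rule fixed at the same time. It takes the targeted and core Polycomb and pluripotency genes, a set of housekeeping genes, the 10 genes with the highest increase and the 10 with the highest decrease among those with FPKM of at least 5 in the higher library (5 each way in the secondary comparisons), and up to 4 members per list with the largest change. Small RNA genes recognised by their symbols and loci named by number were left out of the highest 10. Loci named only by a sequence accession were not recognised as either and stayed in. Which of those genes are printed was decided after the values were seen. Trp53, its neighbours and the division of HOX genes by paralogue number were also chosen after the values were seen.

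Sequencing totals are not part of the table. For transcripts spanning over 2000 bases with low FPKM in both libraries, the most common ratio of the values gave the worth of 1 fragment and from it a relative depth. Relative to the ES wild-type library at 1, depth was 1.20 for ES Eed KO, EB wild type and shCtrl, 0.790 for EB Eed KO and 0.908 for shSetd2. At least 816 transcripts per library entered this estimate.

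The functions were tested on simulated data for the ES Eed KO comparison, with 12635 expressed genes, an assumed spread of 0.2 on the log2 scale and an assumed 25 M fragments. Of 25 genes raised and 25 lowered by a factor of 1.5, the size rule called 1 and 2. At a factor of 2 it called 12 and 14, at 3 it called 25 and 23, and at 4 it called 25 and 25. The changed genes were drawn from those with a mean FPKM of at least 5, so recovery of weaker genes was not simulated. Of 12435 unchanged genes the size rule called 1. That count rests on the assumed spread and is no error rate for these libraries. Between the control ES cells of different lines, the rule called 400 genes higher and 720 lower of 12747. Of 200 random lists of unchanged genes, 193 did not stand apart. These lists came from the same genes as their reference lists, so about this share was set in advance. Lists of genes that vary together were not simulated, nor was transcript length.

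The settings varied were pseudocounts of 0.1 and 5, rescaling by upper quartile, by median of ratios and to equal totals, no filter or an FPKM of at least 5, summed transcripts per symbol, a size rule of 2, and unmatched random lists. Settings added after seeing the data left out small RNA genes, chromosomes 3, 6, 11 and Y, or symbols with several transcripts, or used the E14 shCtrl library as the control of the ES Eed KO library. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

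In the closing section, an explanation is said to be argued against by a median only where the bound set for it lay outside the 95% order-statistic interval of that median. This rule was adopted after the values were seen, in place of first the median alone and then the quartiles, and it treats genes as independent, which they are not.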

Results

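The study asked how the Polycomb repressive complex 2 (PRC2), the enzyme complex that methylates lysine 27 of histone H3, bears on transcription. Transcriptomes were measured in 6 RNA-seq libraries, 1 per group. Wild-type and Eed KO E36 cells, a mouse ES cell line of 129/Ola background, were sampled as ES cells in 15% serum with leukemia inhibitory factor and as EBs. EBs are aggregates that differentiate after removal of that factor. They were kept in hanging drops for 48 hours, exposed from day 2 to day 5 to retinoic acid (the all-trans form, at 0.5 µM) and cultured to day 9. E14 cells, another 129/Ola ES line, received a control (shCtrl) or a Setd2-directed (shSetd2) hairpin by lentivirus and were harvested on day 4 after selection. The FPKM total per library ranged from 452782 in EB Eed KO to 598935 in ES wild type. Between 11871 (shSetd2) and 13171 (EB wild type) genes had an FPKM of at least 1.

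The targeted genes were examined first. Eed, the PRC2 scaffold subunit (NM_021876, mm9 chromosome 7, 97103164 to 97129486), had an FPKM of 72.3 in ES wild type and 77.8 in the library labelled ES Eed KO. In EBs it had 25.04 in wild type and 21.8 in the library labelled EB Eed KO. Eed mRNA was therefore within the size rule of wild type in both libraries labelled KO, at 0.10 in ES cells and -0.19 in EBs, the allele is not given in the labels, and directions drawn from these labels rest on the labels alone. Setd2, the histone H3 lysine 36 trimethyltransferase (NM_001081340, chromosome 9, 110435101 to 110521137), had 16.8 in shCtrl and 2.59 in shSetd2, a difference of -2.31. The other core PRC2 genes Ezh2 and Suz12 had 45.9 and 82.3 in ES wild type against 67.1 and 78.7 in the library labelled ES Eed KO. Over the 12 PRC2 subunit genes, 0 were higher and 0 lower by the size rule in either Eed comparison.

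The comparison of the library labelled ES Eed KO with ES wild type asks what loss of PRC2 does in undifferentiated cells. Parts of the HOX, trophoblast and germ line lists were higher, and part of the p53 targets and several imprinted non-coding RNAs were lower. The germ line and p53 results depended on the control library, as given below. Hoxd13, a posterior limb and genital patterning gene, went from 0.790 to 8.80 FPKM, and Hand1, a trophoblast and heart transcription factor, from 2.26 to 18.4. Meg3, a maternally expressed imprinted non-coding RNA, went from 87.2 to 0.447, and Ccng1, a p53 target encoding cyclin G1, from 104 to 7.50. Of 14772 expressed genes, 417 were higher and 445 lower by the size rule. With upper-quartile rescaling the split was 451 higher and 368 lower, and with median-of-ratios rescaling 433 and 379. Rescaling to equal totals let more genes count as expressed (15925) and moved the median of all genes to 0.07. The split was then 774 higher and 461 lower.

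All directions in this paragraph are relative to a library label that Eed mRNA does not check. Of 39 HOX genes, 14 were higher, 0 lower and 25 within the size rule, with a list median of 0.84 that exceeded all or nearly all random lists (percentile 100). Hoxa10 went from 0.0223 to 4.59, Hoxd9 from 0.0960 to 2.86 and Hoxd8 from 0.0602 to 2.46. Among 113 Polycomb target transcription factors outside the HOX clusters, 17 were higher and 3 lower (median 0.23, percentile 100), with Barx1 at 0.558 and 6.32, Vax2 at 0.412 and 3.63, and Gata2 at 1.74 and 7.34. Of 39 Polycomb target signalling and cell cycle genes, 5 were higher and 1 lower, and the list did not stand apart. Cdkn2a, a cell cycle inhibitor locus, was among them with 14.4 and 42.8. The PRC1 subunit Bmi1 had 2.53 and 10.6, and Cbx8 had 0.749 and 2.84. They were the 2 of 20 PRC1 genes that were higher, with 0 lower.

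Lineage lists moved to different degrees. Of 20 trophoblast genes, 8 were higher and 2 lower (median 0.81, percentile 100). The X-linked homeobox genes Esx1 (0.782 and 15.0), Rhox6 (4.14 and 31.3) and Rhox9 (3.91 and 23.4) were higher, while Krt19, a keratin also on the epithelial list, was lower (62.3 and 15.6). Of 29 germ line and meiosis genes, 8 were higher and 1 lower (median 0.74, percentile 100), with the cohesin genes Smc1b (0.827 and 5.25) and Stag3 (6.51 and 21.01) and the meiotic gene Tex11 (1.46 and 7.32). Against the E14 shCtrl library, a control chosen after seeing the data, the germ line list no longer stood apart, with a median of 0.19 and 1 gene higher and 1 lower. Extraembryonic endoderm genes were higher in 4 of 22 cases and lower in 0 (median 0.38), including Gata4 (0.571 and 2.65), the retinol carrier Rbp4 (1.18 and 5.28) and the basement membrane collagen Col4a1 (16.7 and 46.5). The E14 shCtrl library also stood apart on this list against the same ES wild-type library, with 5 genes higher and 0 lower of 21 (median 0.17). Cardiac and lateral mesoderm genes were higher in 6 of 23 cases and lower in 1 (median 0.42), with Myl7 (5.13 and 19.3) and Nkx2-5 (0.650 and 3.36). The retinoic acid list had 4 higher and 2 lower of 29 (median 0.36).

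Pluripotency genes were not lower. Pou5f1 had 586 in ES wild type and 540.1 in the library labelled ES Eed KO, and Nanog had 146 and 256. On the pluripotency list 7 of 33 genes were higher and 0 lower (median 0.13, percentile 99.8), among them Tbx3 (3.16 and 13.2), Lefty2 (69.2 and 184), Tcl1 (21.3 and 57.1) and Dppa3 (36.6 and 90.6). The E14 shCtrl library, without an Eed mutation by its label, had a pluripotency median of 0.28 against the same ES wild-type library, with 6 genes higher and 3 lower, and Tcl1 in the library labelled ES Eed KO was at -0.51 against shCtrl. The primed epiblast list, genes of the post-implantation state, had 0 higher and 2 lower of 13 (median -0.34, percentile 1.29), with Pou3f1 at 23.5 and 8.03 and Fzd2 at 15.3 and 4.21. Neural progenitor genes had 2 higher and 5 lower of 32 (median -0.22), Zic5 among them with 12.8 and 3.92. Postmitotic neuron genes, with 2 higher and 4 lower of 42, did not stand apart, nor did 35 cell cycle genes, of which 0 passed the size rule either way.

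The lowest list was that of p53 targets, with 11 of 24 genes lower and 2 higher (median -0.98, percentile 0). Perp went from 39.9 to 5.90, Trp53inp1 from 19.7 to 2.91 and Eda2r from 9.48 to 0.640. Trp53 itself (chromosome 11, 69393861 to 69405375), summed over its 2 transcripts, had 284 in ES wild type and 76.2 in the library labelled ES Eed KO. It had 75.1 in the E14 shCtrl library, which carries no Eed mutation by its label. With shCtrl as the control the p53 list had 3 higher and 3 lower and a median of -0.18. Interferon response genes had 0 higher and 7 lower of 28 (median -0.17), including Gbp2 (29.4 and 4.395), Isg15 (9.62 and 1.03) and the immunoproteasome gene Psmb8 (8.70 and 1.38). Of 29 epithelial genes, 0 were higher and 4 lower (median -0.18). Against E14 shCtrl the primed epiblast, neural progenitor, interferon and epithelial medians were positive, at 0.65, 0.24, 0.44 and 0.79. The HOX, trophoblast and Polycomb target transcription factor medians against shCtrl were 0.71, 0.76 and 0.32.

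Imprinted genes had 1 higher and 6 lower of 32 (median -0.17). Of the 6, 3 are maternally expressed RNAs of the Dlk1-Dio3 region of chromosome 12, where Rian went from 96.2 to 0.351 and Mirg from 9.90 to 0.102 beside Meg3 (110779206 to 110809939). Nnat, an imprinted neuronal gene on chromosome 2, was also lower by the size rule. Of the 10 highest decreases, 5 were loci named only by a sequence accession that the table places at the coordinates of Rian and that were listed at 0 in both libraries labelled Eed KO. Outside the lists, the genes with the highest increases included Khdc3, an oocyte and early embryo factor (5.80 and 67.3), Ly6a (0.698 and 13.02), Crxos (1.31 and 12.8), Saa3 (0.606 and 8.12) and the adenylate kinase Ak4 (14.03 and 76.1). Ly6a had 10.5 in E14 shCtrl, so against that control it was within the size rule. Hypoxia and glycolysis genes had 2 higher and 1 lower of 30 (median 0.34, percentile 100). Replication-dependent histones had 1 higher and 0 lower of 30 (median 0.29), a class without poly(A) tails that poly(A) selection captures poorly. Housekeeping genes had 0 of 17 past the size rule.

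In EBs the library labelled EB Eed KO lay further from its wild type than the ES library did. Most postmitotic neuron genes and most HOX genes of the anterior and middle paralogue groups were lower, and the posterior HOX genes and parts of the cardiac, extraembryonic endoderm, epithelial and interferon lists were higher. Tubb3, the neuronal beta-tubulin, went from 290.2 to 1.23, and Hoxb8 from 86.5 to 3.63. Hoxd13 went from 0.435 to 57.3 and Hand1 from 0.782 to 51.2. Of 14772 expressed genes, 1135 were higher and 1450 lower. The median of all genes was shifted by -0.14, and with median-of-ratios rescaling, which moved it to -0.01, the split was 1442 higher and 1147 lower.

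HOX genes divided by position in their clusters, again relative to a label that Eed mRNA does not check. Of the 23 genes of paralogue groups 1 to 8, 0 were higher and 19 lower (median -2.50), whereas all 12 genes of groups 10 to 13 were higher (median 3.43, from 1.48 to 5.34). The 4 genes of group 9 had 2 higher and 1 lower. Hoxa10 had 0.688 in wild type and 34.8 in the library labelled EB Eed KO, Hoxa13 had 0.263 and 21.7, and the antisense transcript Hoxa11os had 0.106 and 21.5, which an unstranded library cannot separate from overlapping sense reads. Over all 39 genes, 14 were higher and 20 lower, and the median was -1.09. Without chromosomes 3, 6, 11 and Y, which removes the Hoxa and Hoxb clusters, 18 genes remained and their median was 1.10. In ES cells groups 1 to 8 had 3 higher and 0 lower (median 0.47) and groups 10 to 13 had 9 higher and 0 lower (median 1.33).

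**Figure D1:**
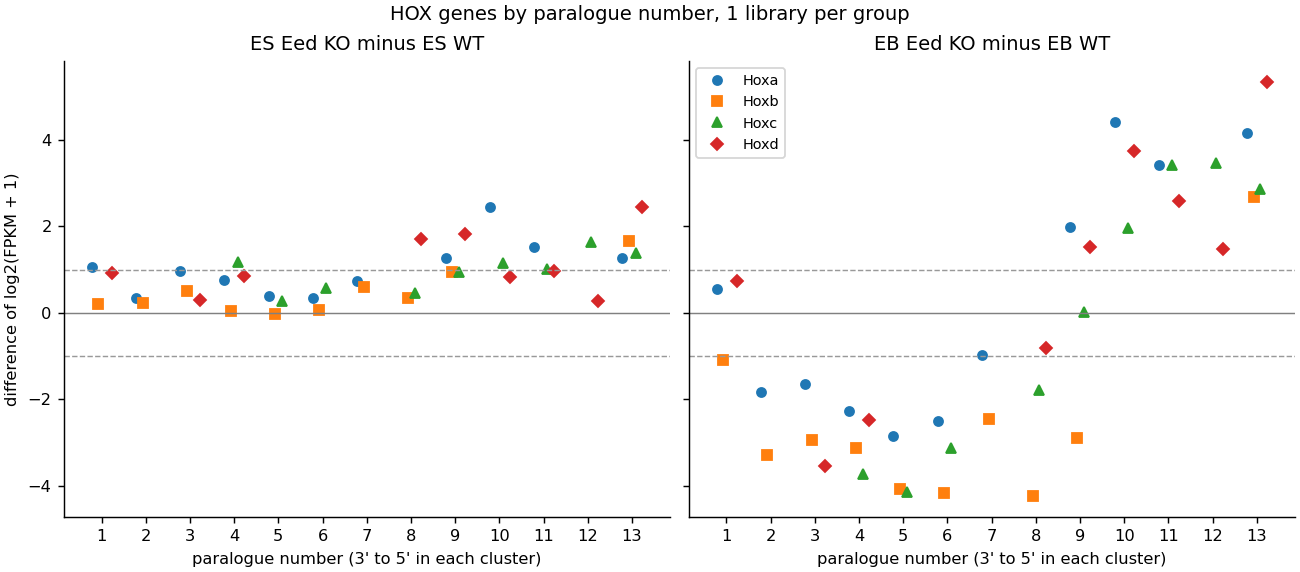
Difference of log2(FPKM + 1) between the library labelled Eed KO and wild type for each HOX gene (y axis) against its paralogue number (x axis), in ES cells (left) and EBs (right), 1 library per group, with symbols by cluster and dashed lines at the size rule of 1. In EBs paralogue groups 10 to 13 lie above 1 while most genes of groups 1 to 8 lie below it on the negative side, and in ES cells 14 of 39 genes lie above.

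The postmitotic neuron list had the lowest median of all. Of 42 postmitotic neuron genes, 31 were lower and 2 higher (median -3.04, percentile 0), with the cytoskeletal genes Stmn3 (41.1 and 0.141) and Ina (41.3 and 0.317). Of 32 neural progenitor genes, 20 were lower and 4 higher (median -1.23, percentile 0). The Notch ligands Dll1 (11.8 and 0.308) and Dll3 (12.3 and 0.748) were lower, and Fabp7, a radial glia marker, had 162 in EB wild type and was listed at 0 in the library labelled EB Eed KO. Wnt1, a midbrain and dorsal neural tube signal, had 34.5 and 0.0921. Pluripotency genes were lower in 22 of 33 cases and higher in 1 (median -1.51), including Pou5f1 (20.8 and 1.21), Sox2 (52.6 and 7.14), Tdgf1 (10.98 and 0.936) and Dppa5a (118 and 1.92).

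Several mesodermal and endodermal lists had more genes higher than lower and stood apart, but not all did. Primitive streak and mesendoderm genes had 0 higher and 3 lower of 9, skeletal muscle genes had 2 higher and 1 lower of 9, and neither list stood apart. Cardiac and lateral mesoderm genes had 12 higher and 2 lower of 23 (median 1.24, percentile 100), with Foxf1 (1.25 and 30.6), Nkx2-5 (0.276 and 9.31) and Tbx20 (0.927 and 14.3). Of the 40 extraembryonic endoderm genes listed only 22 were expressed, with 11 higher and 0 lower (median 0.98). Among the higher were Gata4 (3.30 and 24.8), Gata6 (17.6 and 52.6) and Pdgfra (14.5 and 43.2). Fibroblast and smooth muscle genes had 13 higher and 1 lower of 37 (median 0.84), including Fbln2 (8.29 and 59.4), Timp3 (11.1 and 69.8) and Col1a2 (138 and 589). Mesenchymal transition regulators had 3 higher and 1 lower of 18 (median 0.42). Epithelial genes were higher in 18 of 29 cases and lower in 1 (median 1.17), with the protease inhibitor Spint2 (15.4 and 80.9), the splicing regulator Esrp1 (2.41 and 15.3) and desmoglein Dsg2 (1.94 and 9.93). Trophoblast genes had 9 higher and 2 lower of 20 (median 0.55), and Rhox6, higher in the ES comparison, was lower here (6.06 and 0.405).

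Polycomb target transcription factors outside the HOX clusters had 49 higher and 31 lower of 113 (median 0.63, percentile 100), with Barx1 (0.759 and 42.6) and the hindlimb factor Pitx1 (1.39 and 52.8) higher. Signalling and cell cycle targets had 10 higher and 6 lower of 39 (median 0.52). The chemokine Cxcl14 (2.77 and 110.2) and the neuropeptide precursor Tac2 (1.47 and 42.3) were among the highest increases. Among 20 PRC1 genes, 3 were higher and 0 lower, Bmi1 (10.7 and 29.0) and Rybp (17.9 and 54.5) among them. The retinoic acid list had 4 higher and 7 lower of 29 and did not stand apart, nor did germ line genes with 3 higher and 4 lower of 29, cell cycle genes with 0 higher and 1 lower of 35, or housekeeping genes with 1 higher and 3 lower of 17.

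Interferon response genes had 11 higher and 0 lower of 28 (median 0.87, percentile 100), including B2m (69.9 and 242), Usp18 (1.02 and 7.18) and Ifit1 (0.444 and 4.25). Hypoxia and glycolysis genes had 0 higher and 9 lower of 30 (median -0.76, percentile 0), with Ddit4 (184 and 42.8) and enolase Eno1 (657 and 249). Imprinted genes split into 9 higher and 6 lower of 32. The growth factor Igf2 went from 127 to 1003, whereas Meg3 (244 and 0.801), Rian (191 and 4.02) and Mirg (15.5 and 0.603) were again lower, as was Nnat. Of 24 p53 targets, 14 were lower and 2 higher (median -1.34, percentile 0), with Cdkn1a (81.0 and 5.32), Ccng1 (145 and 14.5) and Aen (28.3 and 3.64). Trp53, summed over its transcripts, had 70.7 in EB wild type and 0.157 in the library labelled EB Eed KO. The Y-linked genes Eif2s3y (25.7 and 0.0628), Ddx3y (10.2 and 0.126) and Uty (4.70 and 0.0178) were also nearly absent there, while the library labelled ES Eed KO had 20.4, 4.52 and 2.17.

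**Figure D2:**
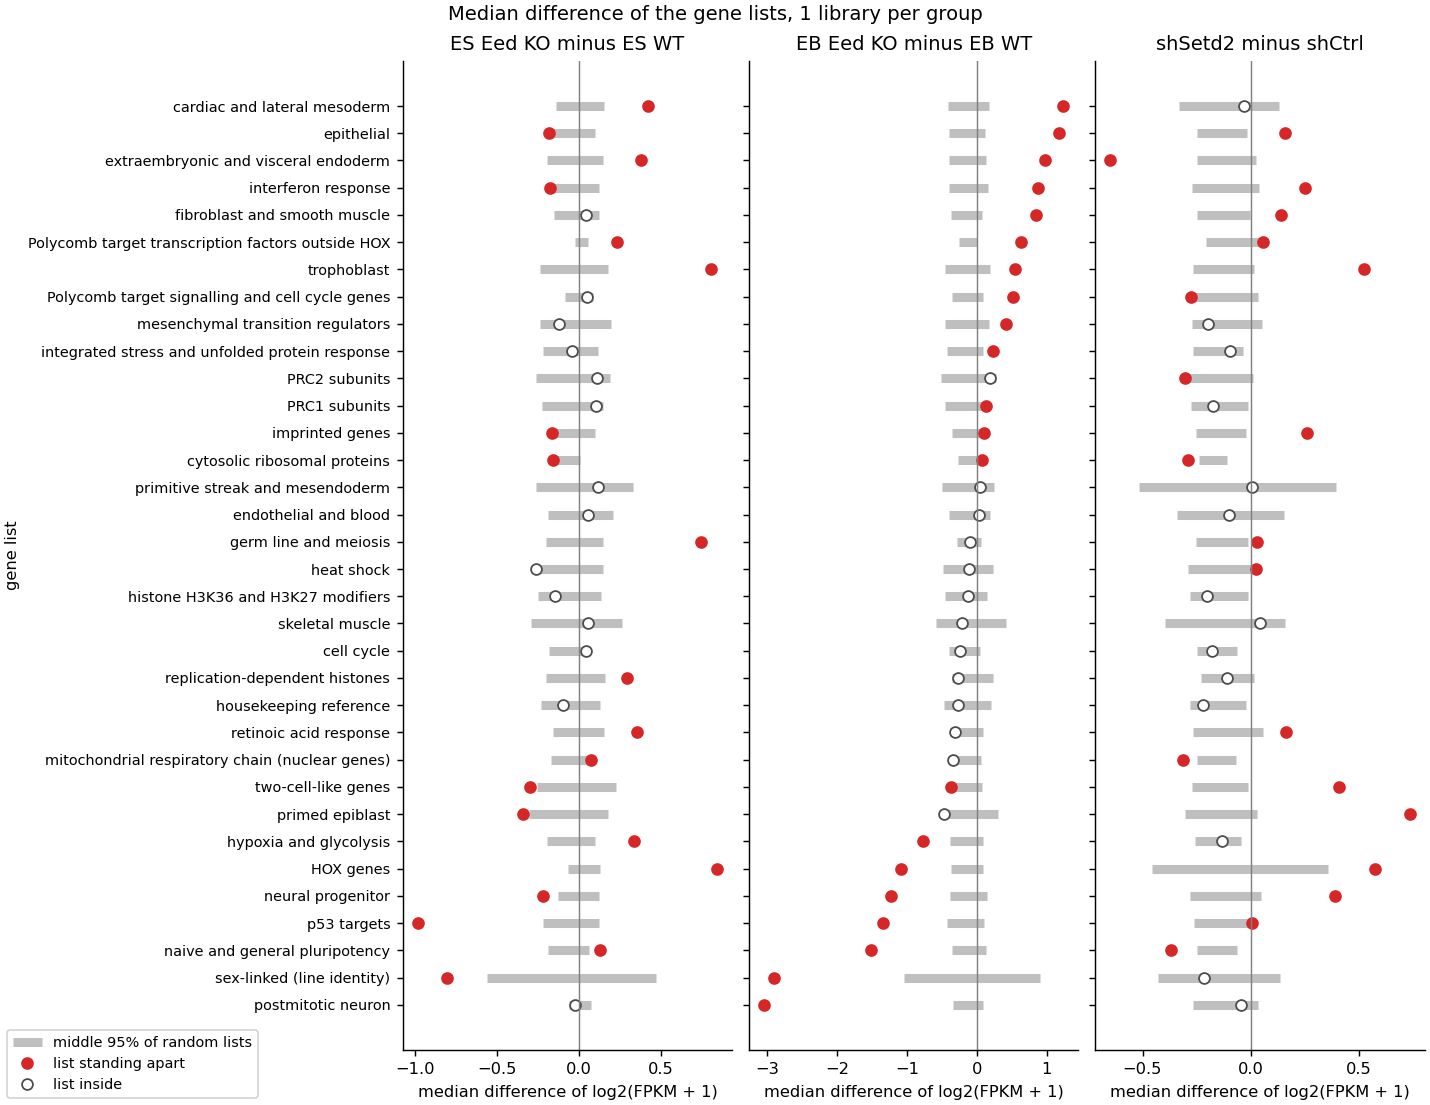
Median difference of log2(FPKM + 1) of each gene list (x axis; lists on the y axis, ordered by the EB comparison) for the libraries labelled ES Eed KO and EB Eed KO and for shSetd2, each against its control, 1 library per group, with grey bars for the middle part of 10000 matched random lists and filled points for lists that stood apart. Postmitotic neuron genes had the lowest EB median at -3.04, p53 targets were low in both Eed comparisons, and extraembryonic endoderm genes were lowest under shSetd2 at -0.65.

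Positions along the genome bear on both Eed comparisons. Relative to all genes with FPKM of at least 5, the median difference in ES cells was 0.39 on chromosome 3, 0.54 on chromosome 6 and -0.49 on chromosome 11. In EBs it was 0.57, 0.47 and -0.53. Chromosome 8, which was shifted between the E14 and E36 lines, had -0.01 in ES cells and -0.08 in EBs. On the 16 remaining chromosomes medians lay between -0.03 and 0.03 in ES cells and between -0.04 and 0.06 in EBs. Chromosomes 3, 6 and 11 held 17.9% of expressed genes, and 25.7% of those higher and 24.3% of those lower in ES cells. In EBs they held 28.9% and 27.5%. Genes named above on these chromosomes include Nanog, Dppa3, Gata2, Vax2, Ezh2 and the Hoxa cluster on chromosome 6, Gbp2 and Sox2 on chromosome 3, and Hand1, Ccng1, Krt19, Trp53 and the Hoxb cluster on chromosome 11. With these chromosomes and Y left out, 310 genes were higher and 336 lower in ES cells, and 807 and 1048 in EBs. The lists of epithelial genes, imprinted genes and the interferon response in the ES comparison then no longer stood apart (percentiles 55.1, 21.9 and 3.58), nor did the PRC1 list of EBs.

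**Figure D3:**
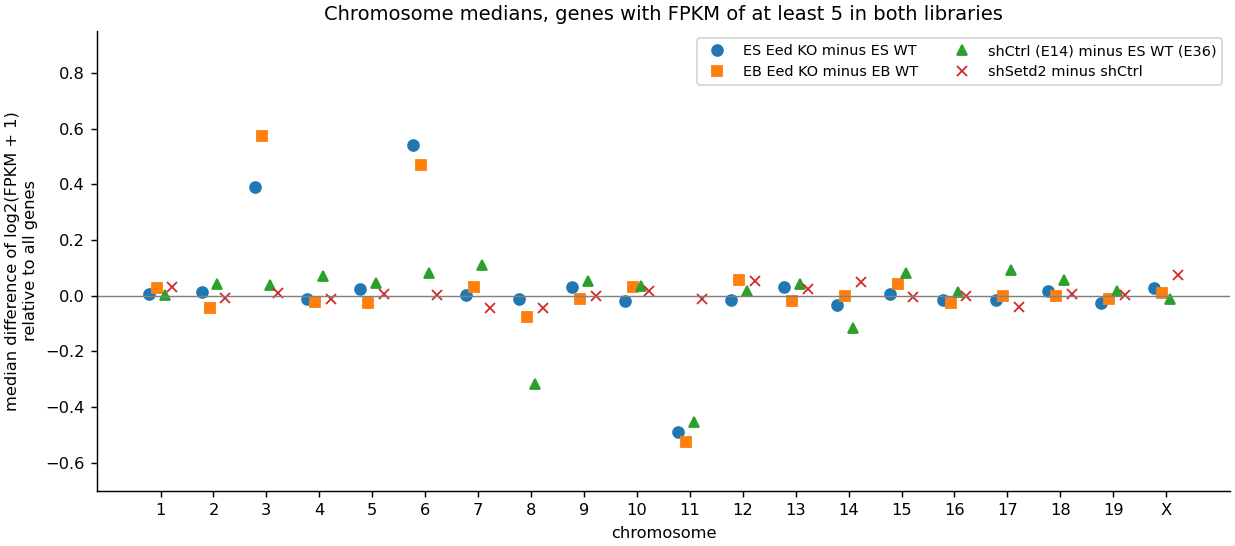
Median difference of log2(FPKM + 1) per chromosome relative to all genes with FPKM of at least 5 in both libraries (y axis) against chromosome (x axis), with a symbol per comparison and 1 library per group. The libraries labelled Eed KO lie above 0 on chromosomes 3 and 6 and below it on chromosome 11, where the E14 shCtrl library lies at -0.45 against the same E36 wild-type library.

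Differentiation itself was compared with Eed present and with the Eed KO label. From ES wild type to EB wild type, 32 of 33 pluripotency genes were lower, and most genes of the HOX, postmitotic neuron, retinoic acid and fibroblast lists were higher. Pou5f1 went from 586 to 20.8 and Col3a1, a fibrillar collagen, from 0.591 to 289. Of 14772 expressed genes, 2855 were higher and 2100 lower. With median-of-ratios rescaling the median of all genes was 0.10 and the split was 3012 higher and 1808 lower. Rescaled to equal totals, with 15925 genes expressed, the median was 0.28 and the split was 4260 higher and 1744 lower.

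On the pluripotency list 32 of 33 genes were lower in EB wild type and 1 higher (median -3.75), with Tdgf1 (459 and 10.98), Utf1 (253 and 5.86), Lin28a (187 and 5.08) and L1td1 (222 and 6.95). The thyrotropin-releasing hormone gene Trh (194 and 3.11) and the threonine dehydrogenase gene Tdh (132 and 2.06) were among the highest decreases. HOX genes had 26 higher and 0 lower of 39 (median 3.04). Groups 1 to 8 had 21 of 23 higher and groups 10 to 13 had 1 of 12 higher, with Hoxb8 (0.210 and 86.5), Hoxb6 (0.0711 and 70.3) and Hoxb9 (0.570 and 82.1). Retinoic acid response genes had 19 higher and 2 lower of 29 (median 2.39), including Nr2f1 (0.159 and 36.9), Meis1 (0.821 and 51.7), Tshz1 (0.504 and 36) and Crabp1 (15.3 and 382). Postmitotic neuron genes had 28 higher and 4 lower of 42 (median 2.06), with Nhlh1 (0.0173 and 23.9) and Nhlh2 (0.0794 and 20.3), and neural progenitor genes had 17 higher and 1 lower of 32 (median 1.32), with Zic1 (0.242 and 61.7) and Fabp7 (0.289 and 162). Fibroblast genes had 28 higher and 2 lower of 37 (median 2.65), and mesenchymal regulators had 13 higher and 0 lower of 18 (median 2.46), Twist1 (2.23 and 29.9) and Cdh11 (2.51 and 98.1) among them.

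Epithelial genes were lower in 21 of 29 cases and higher in 1 (median -1.68), with E-cadherin Cdh1 (197 and 13.5) and Epcam (107 and 10.98). Cell cycle genes had 0 higher and 17 lower of 35 (median -0.97), including Mybl2 (119 and 10.8) and Ccne1 (121 and 28.1). Germ line genes had 0 higher and 15 lower of 29 (median -1.03), Tdrd12 with 37.6 and 1.38. Of 12 PRC2 genes, 0 were higher and 4 lower (median -0.77), including Eed (72.3 and 25.04), Mtf2 (34.3 and 1.05) and Epop (187 and 14.2). Polycomb target transcription factors had 61 higher and 4 lower of 113 (median 1.18), imprinted genes 16 higher and 5 lower of 32 (median 1.06), with Plagl1 (4.61 and 198) and Dlk1 (1.41 and 58.9), and hypoxia and glycolysis genes 15 higher and 1 lower of 30 (median 0.99).

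Between the libraries labelled ES Eed KO and EB Eed KO, 2913 genes were higher and 2738 lower of 14772. With median-of-ratios rescaling the split was 3411 and 2175, and rescaled to equal totals it was 4220 and 2409 of 15925. Trp53, summed over its transcripts, went from 76.2 to 0.157 here, and from 284 to 70.7 in wild type. Of 4 expressed sex-linked genes, among them the Y-linked Eif2s3y, Ddx3y and Uty, 4 were lower here and 0 in wild type. This comparison therefore cannot tell differentiation without Eed from another difference between these libraries. Pluripotency genes were lower in 32 of 33 cases and higher in 0 (median -5.72), with Dppa5a going from 2423 to 1.92, Dnmt3l from 367 to 0.372 and Lefty2 from 184 to 0.122. Fibroblast genes had 29 higher and 1 lower of 37 (median 3.14), including Col1a2 (0.929 and 589) and Col3a1 (0.608 and 421), and cardiac genes had 16 higher and 1 lower of 23 (median 1.66), Hand2 with 0.939 and 54.5. Postmitotic neuron genes, with 6 higher and 12 lower of 42, did not stand apart. Stmn2 went from 69.3 to 3.92 and Nefh from 18.6 to 0.140. HOX genes had 26 higher and 0 lower of 39 (median 1.58), here with 11 of 12 higher in groups 10 to 13 and 11 of 23 in groups 1 to 8. Neural progenitor genes had 15 higher and 6 lower of 32 and did not stand apart, and cell cycle genes had 0 higher and 23 lower of 35 (median -1.28). Genes higher in both differentiation comparisons numbered 1714, against 563.0 for independent lists, and those lower in both 1509, against 389. In opposite directions there were 56 and 26 genes. Across genes, which are not independent replicates, the differences correlated with Pearson r 0.66 and Spearman rho 0.76.

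The Eed effects in ES cells and EBs were then set against each other. They share no library, but the Eed KO label and the wild-type label recur in both. A difference between these cells other than Eed would therefore enter both effects. The chromosome shifts given above and the lower p53 targets were present in both comparisons. The overlaps that follow therefore cannot tell a shared effect of Eed from a shared difference between the lines. Higher in both were 105 genes against 32.0 for independent lists, and lower in both 120 against 43.7. Higher in ES and lower in EBs were 43 genes against 40.9, and the reverse held for 39 against 34.2. Across genes r was 0.16 and rho 0.23. Subtracting the ES effect from the EB effect left 1349 genes higher and 1493 lower by the size rule, with a median over all genes of -0.11. The near absence of Trp53 and Y-linked mRNA in the library labelled EB Eed KO enters this subtraction, and its cause was not tested. The postmitotic neuron list had the lowest median of this difference among those fixed, at -2.95, with 32 genes lower and 2 higher of 42. Tubb3 had a value of -7.20, Igfbpl1 -6.21 and Dppa5a -6.24, while Col8a2 had 4.198, Col1a2 4.202 and Tac2 3.95. Of 24 p53 targets 3 were higher and 6 lower, and the list did not stand apart.

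Knockdown of Setd2 in E14 cells asks what lower H3 lysine 36 methyltransferase expression does in ES cells. A few interferon response and primed epiblast genes were higher by the size rule and some extraembryonic endoderm genes were lower, while most members of these lists stayed within it. Gbp2 went from 0.791 to 10.7, Pou3f1 from 3.87 to 14.1 and Gata6 from 3.22 to 0.821. Of 12317 expressed genes, 87 were higher and 210 lower, and without small RNA genes, a setting chosen after seeing the data, 48 were higher and 135 lower. The median of all genes was shifted by -0.13, and with upper-quartile rescaling, which moved it to 0.03, the split was 138 higher and 156 lower.

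Interferon response genes had 4 higher and 0 lower of 18 (median 0.25, percentile 99.98), including Psmb8 (0.624 and 5.67) and Irf1 (7.58 and 20.8). The related GTPases Gbp2b (0.498 and 6.04) and Irgm1 (1.41 and 5.34) were also higher. Primed epiblast genes had 3 higher and 0 lower of 13 (median 0.73, percentile 100), with Lef1 (2.51 and 8.47) and the de novo methyltransferase gene Dnmt3b (34.7 and 72.7) beside Pou3f1. Fgf5 had 0.562 and 1.75, within the size rule. Extraembryonic endoderm genes had 0 higher and 6 lower of 20 (median -0.65, percentile 0), with Apoe (454 and 181) and Spink1 (22.9 and 5.25). Pluripotency genes had 0 higher and 2 lower of 33 (median -0.37, percentile 0), the naive factors Tcl1 (81.9 and 35.5) and Tfcp2l1 (48.6 and 21.7). Esrrb had 142 and 71.0, Pou5f1 715 and 493, and Nanog 241 and 207, all within the size rule. Trophoblast genes (0 of 19 past the rule, median 0.52), neural progenitor genes (0 of 17, median 0.39) and two-cell-like genes (0 of 18, median 0.41) stood apart without any member past the size rule. Nes had 2.24 and 5.25 and Sox11 had 3.45 and 7.21.

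Genes with the highest decreases included the proteases and metabolic genes Napsa (11.9 and 2.77), Cpt1a (22.4 and 7.59), Sirt3 (6.55 and 1.51) and Pgam1 (577 and 240.0), and also Parvb (36.3 and 10.7), Cd37 (6.74 and 1.56), Fam25c (89.0 and 30.2) and S100a13 (18.3 and 5.81). Pim2, a serine kinase gene (18.4 and 69.2), and the non-coding RNA Platr5 (6.996 and 24.1) were among the highest increases. Imprinted genes had 1 higher and 0 lower of 27 (median 0.26), the higher gene being Igf2 (9.41 and 22.3), and the retinoic acid list had 1 higher and 0 lower of 17 (median 0.16), the higher gene being Crabp2 (4.93 and 12.3). Ribosomal protein genes (median -0.29) and nuclear genes of the respiratory chain (median -0.31) lay below the all-gene shift with 0 genes past the rule. Of 12 PRC2 genes 0 passed the rule, Eed with 127 and 101, but the list stood apart (median -0.30, percentile 2.22). Of 19 modifiers of H3 lysine 36 and 27 only Setd2 was lower and 0 were higher. Epithelial and housekeeping genes had 0 members past the rule. The epithelial list stood apart (median 0.16, percentile 100) and the housekeeping list did not.

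Genes past the rule in both the ES Eed comparison and the Setd2 comparison went in opposite directions more often than in the same one. Of 12116 genes expressed in both, 33 were higher with the Eed KO label and lower under shSetd2, against 4.71 for independent lists, and 25 were lower and higher, against 2.31. In the same direction there were 11 higher (against 1.97) and 19 lower (against 5.51). With the EB Eed comparison, 13 were higher in both (against 4.28 for independent lists) and 41 lower in both (against 14.5). In opposite directions, 29 were higher with the Eed KO label and lower under shSetd2 (against 10.2), and 16 the reverse (against 6.07). The excess was thus similar in every direction, at ratios from 2.64 to 3.03. Without small RNA genes, the ES pair shared 10 genes in the same direction and 34 in opposite ones, and the EB pair 27 and 24. Across genes r was -0.04 for the ES pair and -0.01 for the EB pair.

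The yardstick of E14 shCtrl against E36 ES wild type, neither with its Polycomb or Setd2 gene targeted, had 400 higher and 720 lower of 12747 expressed genes. The count was thus above that of the ES Eed comparison. Many of the gene lists also stood apart here, among them p53 targets and the interferon, epithelial and primed epiblast lists. Standing apart is therefore not by itself particular to Eed or Setd2. With median-of-ratios rescaling, which removed an all-gene shift of -0.10, it was 463 and 567. Hprt had 114 in E36 and 0.567 in E14, and Mid1 had 2.86 and 288. Nupr1 (3.48 and 58.0), Napsa (1.27 and 11.9), Ly6a (0.698 and 10.5) and Gpr19 (0.0120 and 5.23) were higher in E14. Of 23 p53 targets 11 were lower and 1 higher in E14 (median -0.97), Ccng1 with 104 and 14.04 and Perp with 39.9 and 6.36. Lower lists included interferon response (0 higher and 10 lower of 22, median -0.92), with Gbp2 at 29.4 and 0.791 and Isg15 at 9.62 and 0.339, epithelial (0 and 16 of 26, median -1.12), with Krt19 at 62.3 and 4.53, and primed epiblast (0 and 8 of 13, median -1.30), with Pou3f1 at 23.5 and 3.87. Two-cell-like genes had 13 higher and 0 lower of 18 (median 1.10), Tdpoz4 with 1.72 and 8.69, and integrated stress genes 6 higher and 1 lower of 25 (median 0.40).

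Change by expression level was examined in 5 bins of mean expression. From the lowest to the highest bin, the median difference of the library labelled ES Eed KO from wild type went from 0.01 to -0.07, and that of EB Eed KO from -0.06 to -0.18. Differentiation had a steeper slope, from 0.24 to -0.35 in wild type and from 0.17 to -0.45 with the Eed KO label. The shSetd2 medians were -0.08 and -0.14, and those of shCtrl against ES wild type -0.14 and -0.06.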

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

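Tests of the Trp53 neighbours, of genes flanking Meg3, of windows along chromosomes and of strongly expressed genes were set before their results were seen, and the other tests of explanations were chosen only after.

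The following results went opposite ways in ES cells and EBs between the library labelled Eed KO and wild type. With 1 library per group, the difference between the effects was not tested. List medians stood apart in both comparisons and differed, EB minus ES, by -1.64 for pluripotency genes, -1.93 for HOX genes, -1.10 for hypoxia and glycolysis genes, 1.36 for epithelial genes, 1.05 for interferon response genes, 0.27 for imprinted genes and 0.23 for ribosomal protein genes. Over all expressed genes, 43 were higher in ES cells and lower in EBs by the size rule, and 39 the reverse. Only the genes printed for these comparisons, with values above 0 in all E36 libraries, were flagged. Among them, those past the size rule in opposite directions were Col1a2 with a difference of 4.202, Isg15 with 3.60, Dppa3 with -3.55, Lefty2 with -3.62, Rhox6 with -4.98 and Rhox9 with -4.18. The ribosomal protein medians were -0.16 in ES cells and 0.07 in EBs. Several of these contrasts depended on the setting. Without chromosomes 3, 6, 11 and Y the EB HOX median was 1.10, the same sign as in ES cells, and the ES epithelial, imprinted and interferon lists no longer stood apart. With E14 shCtrl as the control, the ES values were 0.79 for epithelial genes, 0.44 for interferon response genes and 0.60 for Isg15, the same sign as in EBs. Of the 12 genes of HOX paralogue groups 10 to 13, 9 were higher in ES cells and 12 in EBs, with 0 lower.

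The medians of chromosomes 3, 6 and 11 differed between the Eed KO and wild-type libraries in ES cells and in EBs. Release of silent Polycomb targets as the whole cause on chromosomes 3 and 6 is argued against by genes with a mean FPKM of at least 50, whose lowest median was 0.46, with intervals of the 4 medians reaching no lower than 0.35. A difference in the copy number of whole chromosomes between the lines is a candidate explanation. Of 23 windows of 20 Mb, 95.7% had the sign of their chromosome in both comparisons, so the shifts were spread along the chromosomes. On chromosome 3 in EBs the windows ranged from -0.10 to 1.06. The chromosomes were picked for their shifted medians in these same libraries, which made that sign likely in advance. The windows therefore cannot tell copy number from another broad shift. Loss of Eed as the cause on chromosome 11 stays open and cannot be told apart from line differences, since the E14 shCtrl library, of another line, lay at -0.45 against E36 wild type there.

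Of 24 p53 targets, 11 were lower in the library labelled ES Eed KO and 14 in that labelled EB Eed KO. A state of the ES wild-type library alone cannot account for the EB part of the pattern, since the EB comparison shares no library with it and had a median of -1.34, with an interval up to -0.59. For the ES part it stays open. Loss of a segment of chromosome 11 around Trp53 in the library labelled EB Eed KO stays open. It does so only under the interval rule adopted after the values were seen. The 13 expressed neighbours within 100 kb had a median of -0.95, just above the bound set beforehand for ruling a loss out. The interval of that median went from -1.46 to -0.28. Of these neighbours, 5 were lower by the size rule. The adjacent gene Wrap53 went from 13.1 FPKM in EB wild type to 4.23, Eif4a1 from 590 to 214 and Atp1b2 from 23.4 to 35.6, while Sox15 went from 1.35 to 0.0432. Wrap53, Eif4a1 and Atp1b2 were thus not lost from all cells of that library. A loss of only some copies, or one confined to Trp53, was not tested. The neighbour median also includes the shift of chromosome 11, whose own EB median was -0.68. Trp53 went from 70.7 to 0.157. Loss of Eed itself stays open too and cannot be told apart from line differences, since both E14 libraries lay nearer to the ES Eed KO than to the E36 wild-type library for 15 of 24 targets.

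Meg3, Rian and Mirg were low in both libraries labelled Eed KO, with Meg3 at 0.447 in ES cells. Loss of a chromosome segment reaching the genes on either side was examined in the 13 expressed non-imprinted genes within 1 Mb. It was set beforehand to give medians of -0.5 or lower, and to be ruled out by medians above -0.3 in both comparisons. The medians were -0.16 in both, so the rule set beforehand went against a loss. A loss stays open only under the interval rule adopted after the values were seen. The interval reached -0.43 in ES cells and -0.76 in EBs. By the size rule, 0 of these genes were lower in ES cells and 2 in EBs. Dlk1, an imprinted gene of the same region, was left out of these genes. It rose by 7.85 from the library labelled ES Eed KO to that labelled EB Eed KO, and by 4.63 in wild type. Dlk1 was thus not lost from all cells of the EB library, and a loss of only some copies was not tested. An effect of Eed loss on the imprinted region and another difference between the lines cannot be told apart, as both libraries come from cells of the same label.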

How the results depend on the processing

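The settings that left out small RNA genes, chromosomes 3, 6, 11 and Y, or symbols with several transcripts, and the E14 control, are tests chosen only after results were seen. No paired analysis was run, and each group has 1 library. The cause was not tested where a value moved.

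A pseudocount of 0.1 gave 1824 genes past the size rule for the library labelled ES Eed KO, 570 for shSetd2 and 1877 for shCtrl against ES wild type. A pseudocount of 5 gave 308 for ES Eed KO, 1079 for EB Eed KO, 2357 for EB against ES wild type, 2880 for EB against ES Eed KO, 1136 for the difference of the Eed effects, 151 for shSetd2 and 422 for shCtrl against ES wild type. A size rule of 2 gave, in that order, 160, 603, 1431, 1657, 693, 101 and 197. With a pseudocount of 5, genes shared in the same and in opposite directions numbered 75 and 30 for the Eed effects in ES cells and EBs, 1439 and 34 for differentiation, 19 and 32 for ES Eed KO with shSetd2, and 29 and 24 for EB Eed KO with shSetd2. Leaving out small RNA genes gave 183 genes for shSetd2, and its overlaps became 10 and 34 with ES Eed KO and 27 and 24 with EB Eed KO.

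With E14 shCtrl as the control of ES Eed KO, list medians changed sign to 0.65 for primed epiblast, 0.24 for neural progenitor, 0.79 for epithelial and 0.44 for interferon response genes. Differences changed sign to -0.51 for Tcl1, -0.27 for Stag3, 1.59 for Gbp2, 0.60 for Isg15, 0.55 for Psmb8, 1.58 for Krt19, 0.89 for Pou3f1 and 0.0390 for the highest transcript of Trp53. In all, 21 of 53 differences of named genes stayed the same with this control, 24 moved and 8 changed sign. Without chromosomes 3, 6, 11 and Y, medians changed sign to -0.10 for PRC1 subunits and 1.10 for HOX genes in EB Eed KO, and to -0.0799 for epithelial genes under shSetd2. With an FPKM of at least 5, the extraembryonic endoderm median of shCtrl against ES wild type changed sign to -0.0124 over 9 genes.

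Over all settings, 67 of 85 gene counts stayed within a factor of 1.5 and 18 moved, and all 85 counts of lists standing apart stayed within it. Of 1208 list medians 1138 were the same, 62 moved and 8 changed sign, and of 2478 differences of named genes 2140 were the same, 330 moved and 8 changed sign. A setting that only leaves genes out cannot change the difference of a gene that remains. The 2140 therefore include results fixed in advance. These are 232 without a filter, 228 at an FPKM of at least 5, and 230, 165 and 178 without small RNA genes, the chromosomes or symbols with several transcripts.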

Other observations

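Some lists fixed beforehand belong to no account above. Two-cell-like genes were lower from ES to EB wild type in 11 of 15 cases and higher in 0, with a median of -1.60. Heat shock genes had 0 higher and 7 lower of 14 in the same comparison and stood apart. Primitive streak genes had 5 higher and 2 lower of 9, skeletal muscle genes 2 higher and 3 lower of 9, and endothelial and blood genes 2 higher and 5 lower of 20, and none of these 3 lists stood apart. Modifiers of H3 lysine 36 and 27 had 3 higher and 1 lower of 19. Integrated stress genes in the library labelled EB Eed KO had 1 higher and 2 lower of 25 against EB wild type, yet their median of 0.23 stood apart at percentile 99.7.

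The Y-linked genes Eif2s3y, Ddx3y and Uty had 36.9, 10.2 and 4.44 FPKM in ES wild type, 20.4, 4.52 and 2.17 in the library labelled ES Eed KO and 0.0628, 0.126 and 0.0178 in that labelled EB Eed KO. Chromosome 8 had a median of -0.32 relative to all genes in E14 shCtrl against E36 ES wild type. Mid1 had 288 in shCtrl and 161 in shSetd2 and at most 3.34 in the 4 E36 libraries. Small RNA genes, which a poly(A) kit does not target, took between 14.4% and 19.5% of the FPKM total.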
